A study of Oryza sativa with 3 samples.

How the data were processed

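Leaf sheath RNA of RDD4-overexpressing and wild-type rice was compared on 3 two-colour Agilent arrays, 1 per independent overexpressing line. Per the labels' protocols, plants grew in soil at 28 °C in days of 16 h of light and nights of 8 h. Their total RNA was isolated with a commercial kit for plants, and 400 ng were amplified linearly and labelled. Per the labels, Cy5 marked the overexpressing line and Cy3 the wild type on every array, so there was no dye swap. The titles also give a time of 1 h, which the labels do not explain. Per the labels, the replicates are independent lines, so p-values measure the spread between lines. Whether the wild-type RNA was shared by the arrays or came from separate plants is not given in the sources used here.

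The deposited scanner files hold spot intensities, and per the file headers they were made with Agilent Feature Extraction 10.5.1.1. The mean and local background intensities are as scanned. The processed intensities were, per the file headers, background-subtracted, corrected for spatial trends and dye-normalised by that program, with substitute values for dim spots. Per the file headers, the log ratio is the log10 of processed Cy5 over Cy3. The authors' series matrix held the same log10 ratios, equal to those of the scanner files at all 45151 spots of each array (largest difference 0), so their scale, direction and lack of further centring are known. Their medians were -0.000585, 0 and 0 for lines 2, 3 and 4. Each array had 45151 spots, of which 43734 were gene spots with 42477 different probes. Of these probes, 41908 carried a locus name for 29690 genes. The other probes were 510 for microRNA loci and 59 others without a locus name. Gene names are the descriptions of the array's design, which can be old. The reference table used here paired no locus of the array with a symbol, and no genome was used, so no positions are given.

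Files were read in R 4.3.3 and analysed with limma 3.58.1. Mean intensities were corrected with normexp on the median local background (offset 50, fitted on all spots) and normalised within each array by loess, with control spots at weight 0. No normalisation between arrays was applied. Spots marked by the scanner program as non-uniform or as population outliers were left out (132, 61 and 71 spots for lines 2, 3 and 4), and replicate spots of a probe were averaged. A probe was kept if it was well above background on all 3 arrays in Cy5 or on all 3 in Cy3, and the brightest kept probe stood for its gene, which left 23871 genes. The log2 ratios were tested against 0 with lmFit and eBayes, with 2 residual degrees of freedom plus 3.28 estimated across genes, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Changes of at least 2-fold were counted at an absolute log2 ratio of at least 1.

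The median Cy5 and Cy3 intensities of gene spots were 1180 and 561 for line 2, 1260 and 546 for line 3 and 1210 and 548 for line 4, over median local backgrounds of 56.0 and 24.5, 56.5 and 26.0 and 56.0 and 25.0. All 3 arrays lay on 1 slide, so slide and scan could not be tested as batches. On the line 2 array, 4 adjacent spots had local backgrounds of up to 105292 in Cy3 and 10523 in Cy5. They raised the noise that normexp estimates for that array from 1.03 to 1250 in Cy3 and from 2.09 to 205 in Cy5, which pulls ratios of dim spots towards 0. After the data were examined, an analysis was added in which a local background above 1000 was replaced by the median of its array and channel. Its total counts are given beside the planned ones, and its counts and values for a part of the lists and genes. Where a tested probe was not well above background on any array in 1 channel, a bound on the mean of the arrays is given as at least N-fold, unless it equals the fitted mean. It sets the mean of the bright channel against the higher of the dimmest signal well above background and the probe's own, per array, after loess and quantile normalisation of the average signal, and it is open to dye bias.

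At the outset, 45 gene lists were fixed by locus or by words of the description. The 42 with at least 5 tested genes were tested with camera (preset correlation 0.01), adjusted over the lists by Benjamini-Hochberg, with camera with an estimated correlation and fry beside it. Genes were named by a rule fixed at the same time. It took the 12 largest positive and the 12 largest negative mean log2 ratios among genes past the threshold with an absolute log2 ratio of at least 1 and the same sign in all 3 lines. A direction with fewer was filled by the smallest unadjusted p among genes of that size and sign pattern, said not to pass. For each list called or with at least 3 changed members it took up to 4 members with the smallest p, of which a part is named, and it took every changed Dof gene. The same rule was applied to the added analysis. Probe sequences were compared for shared stretches of 20 bases.

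The pipeline was tested on simulated signals for 23871 genes of the comparison, with a part of the genes changed and a dye trend with brightness. At a log2 size of 2 it recovered 100% of 66 genes, at 1 85.1% of 67 and at 0.5 10.4% of 67, with 14 false calls, and fitted ratios were 0.841 to 0.925 times the true ones. With the 4 high local backgrounds placed on 1 simulated array, which is the state of the planned analysis, it recovered 28.8%, 13.4% and 0% of them, with 0 false calls, and fitted ratios were 0.669 to 0.77 times the true ones. The tests, the gene lists, the naming rule and the following alternatives were chosen before the data were examined. The alternatives changed the background correction, the normalisation within and between arrays, the filter, the choice of probe, the variance estimate and array weights, used the separate channels or the deposited ratios, and left out each line.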

Results

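Gene expression was measured in leaf sheaths of 2-week-old rice plants (Oryza sativa, cultivar Nipponbare) that overexpressed RDD4, a member of the Dof family of zinc-finger transcription factors, and of wild-type plants. The leaf sheath is the lower part of the grass leaf, which wraps the stem. Labelled RNA of overexpressing plants (Cy5) and of the wild type (Cy3) was hybridised together on each of 3 two-colour Agilent rice arrays. The 3 arrays are 3 replicates, each from an independent transgenic line, namely lines 2, 3 and 4. Each array held 43734 gene spots, of which 81.5%, 83.5% and 83.2% were well above background in Cy5 for lines 2, 3 and 4, and 79.0%, 79.9% and 78.7% in Cy3. No spot was saturated, and 23871 genes were tested. A positive log2 ratio means more signal in the overexpressing plants, and values are means ± SD over the 3 lines. With 3 arrays, their number limits the precision.

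The design asks which genes differ between leaf sheaths that overexpress RDD4 and wild-type leaf sheaths. The largest rises were those of a lipoxygenase gene, a chalcone synthase gene, a hypothetical gene and a cytochrome P450 gene, and thionin genes fell most. The lipoxygenase L-2 gene Os03g0738600 was 25.3-fold higher (log2 ratio 4.66 ± 0.49, n = 3), and the chalcone synthase gene Os07g0526400 18.6-fold higher (4.22 ± 0.61). The thionin gene Os06g0514100 fell by 4.43 on the log2 scale (SD 0.86), and Os06g0514800, described as a phoratoxin, which is also a thionin, fell by 3.97 (SD 1.14). In all, 548 genes were higher and 335 lower at a Benjamini-Hochberg adjusted p under 0.05 in limma, and 108 of the higher and 11 of the lower genes changed at least 2-fold. All 119 genes changed at least 2-fold had the same sign in every line. With 3 arrays a call at this threshold requires that, so it is no separate sign of agreement.

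These counts depended strongly on 4 adjacent spots of the line 2 array with a very high local background, found after the data were examined. With those 4 local backgrounds replaced by the array's median, limma with Benjamini-Hochberg adjustment called 2204 genes higher and 1567 lower, of which 291 and 48 changed at least 2-fold, and 864 of the 883 genes were called again with the same sign. That analysis in turn called 1095, 429 and 1107 genes without lines 2, 3 and 4, and 10311 with median centring. The filter let in 379 genes well above background on all arrays in Cy5 and on none in Cy3, against 13 the other way. Of these, 157 were called higher and 13 lower there. With both channels required to be well above background, 2017 genes were higher and 1546 lower. The majority of higher genes did not hold in every setting, with 1478 higher and 2021 lower in the planned analysis under median centring and 1460 and 1489 by the scanner's LogRatio (limma, Benjamini-Hochberg). Without line 3 the planned analysis called 27 genes, without line 4 120 and without line 2 1095, and scaling the spread of the arrays to each other left 0 genes in limma (4008 at an unadjusted p under 0.05). The same dye marked the overexpressing plants on every array, so a dye effect on single probes is not separated from the genotype, and if the arrays shared wild-type RNA, which the labels do not tell, the ratio against 0 leaves out the spread of the wild type.

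**Figure D1:**
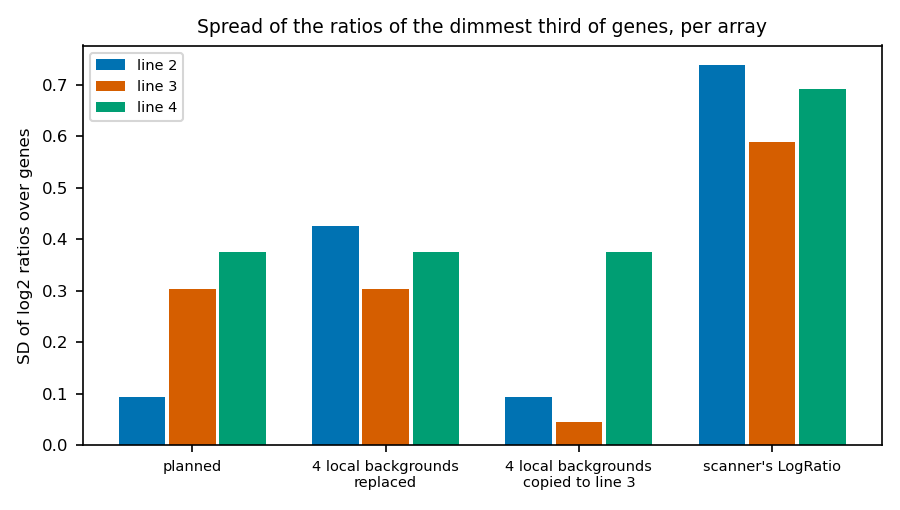
SD of the log2 ratios (y axis) over the 7957 dimmest of the genes tested, 1 bar per line, for 4 settings (x axis). In the planned analysis line 2 had an SD of 0.0939 against 0.303 and 0.374 for lines 3 and 4, and with the 4 local backgrounds replaced 0.425.

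The jasmonate list, 36 measured genes for synthesis of and response to this wound and defence hormone, moved up as a group (median log2 ratio 0.23; camera in limma, Benjamini-Hochberg adjusted p = 0.000507). The call was lost with an estimated correlation between genes (p = 0.239, adjusted p = 0.912 with an estimated correlation). With 3 arrays that test rests on 2 residual degrees of freedom and could hardly call any list, here or below. Of its members 13 rose, 1 fell and 22 did not pass. Adjusted over the list alone, 17 rose and 2 fell. Lipoxygenases, which oxygenate polyunsaturated fatty acids, led the list. Their descriptions do not tell whether these lipoxygenases serve jasmonate synthesis. Besides Os03g0738600, the lipoxygenase genes Os12g0559200 (2.82 ± 0.25) and Os12g0560200 (2.54 ± 0.29) rose in every line. Os09g0439200, which encodes a ZIM domain protein, a family that holds repressors of jasmonate signalling, rose by 0.97 ± 0.22 (limma, Benjamini-Hochberg adjusted p = 0.0231). Allene oxide synthase Os02g0218700, an enzyme of jasmonate synthesis, had a log2 ratio of 2.66 and did not pass in the planned analysis. With the 4 local backgrounds replaced it rose by 3.58 ± 0.52 (adjusted p = 0.0029 in limma with Benjamini-Hochberg adjustment). Its wild-type signal was well above background on only 2 arrays, so the size of this rise rests partly on background.

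Among 130 genes of the pathogenesis-related list, 11 rose, 1 fell and 118 did not pass, or 29 and 8 for higher and lower adjusted over the list alone. The list moved up (median 0.09; camera adjusted p = 0.048, Benjamini-Hochberg, limma), which was lost with an estimated correlation (p = 0.0997, adjusted p = 0.773 with an estimated correlation) and passed in 12 of 20 settings. By a word of the description the list also took 29 genes of ERF domain transcription factors, which are no pathogenesis-related proteins, and 3 of these rose. Of the other 101 genes, set apart after the results were seen, 8 rose and 1 fell. Os12g0555000, a Bet v I family gene of the kind that holds the pathogenesis-related proteins of class PR-10, rose by 3.20 ± 0.47, and its 2 probes gave 2.26 and 3.20. With the 4 local backgrounds replaced it rose by 3.72 ± 0.96, with line 2 at 4.68. The ERF domain genes that rose included Os01g0868000 (1.58 ± 0.26) and Os10g0560700 (0.48 ± 0.0007). The member that fell was Os06g0514100, one of the thionins, small cysteine-rich antimicrobial proteins. Another thionin gene, Os06g0512700, had a log2 ratio of -3.15 ± 1.57 and did not pass (adjusted p = 0.0527, limma with Benjamini-Hochberg adjustment), and with the 4 local backgrounds replaced it fell by 3.83 (SD 0.46; adjusted p = 0.00194). The probes of these thionin genes shared no stretch of 20 bases with a probe of another gene, and binding of other thionin transcripts to them was not tested.

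The other genes with the largest rises were the Bowman-Birk trypsin inhibitor gene Os01g0124200 (2.49 ± 0.67), the beta-glucosidase aggregating factor gene Os12g0247700 (2.49 ± 0.08), the cytochrome P450 gene Os10g0515900 (3.36 ± 1.26), the glycine-rich protein gene Os07g0511100 (3.05 ± 0.88) and the hypothetical genes Os07g0511400 (3.87 ± 0.88), Os11g0211800 (3.17 ± 0.38) and Os03g0431600 (2.49 ± 0.59). Line 2 lay lowest for Os07g0511400, at 2.86, and at 4.08 with the 4 local backgrounds replaced. Apart from the thionins, the lower genes of the planned analysis changed less. They were the transcriptional coactivator gene Os06g0592500 (-1.66 ± 0.13), the ribonuclease T2 gene Os09g0537700 (-1.61 ± 0.30, all 12 probes between -1.84 and -1.56), the ubiquitin gene Os09g0483400 (-1.33 ± 0.25), the metallothionein gene Os05g0202800 (-1.23 ± 0.57), the chalcone synthase family gene Os03g0382100 (-1.16 ± 0.42), the male sterility family gene Os04g0354600 (-1.13 ± 0.24), the glutathione transferase gene Os10g0528900 (-1.10 ± 0.41) and Os09g0498500, with a NAD-binding site (-1.09 ± 0.24). Os03g0169600, a Dof gene, completed the 11.

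**Figure D2:**
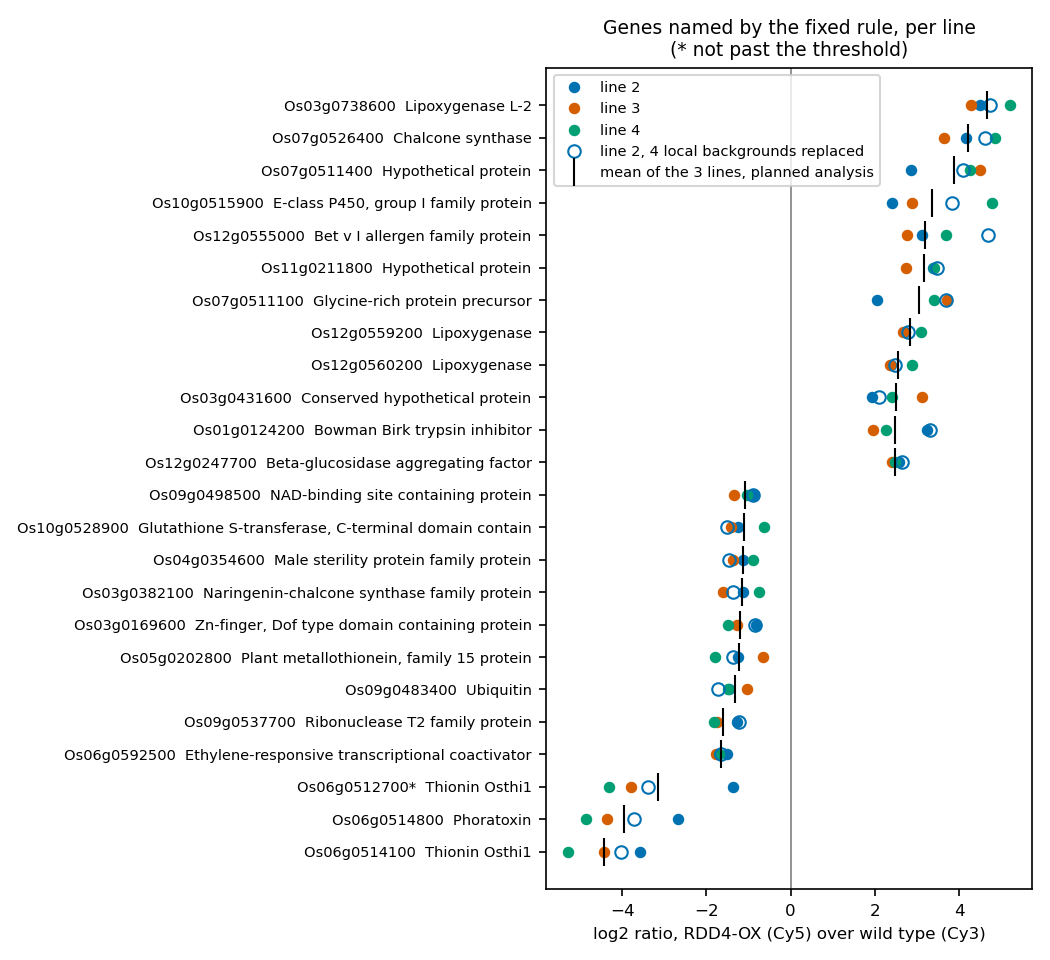
Log2 ratios of RDD4-OX over wild type (x axis) for the 24 genes that the fixed rule took by size (y axis), 1 filled point per line, a bar for the mean of the planned analysis and an open circle for line 2 with the 4 local backgrounds replaced. The rule takes only genes with all lines on the same side of 0, so that agreement was set by the selection. The open circles of the thionin genes lie nearer to lines 3 and 4.

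WRKY transcription factor genes, many of which act in defence responses, moved up as a group of 62 (median 0.20; camera adjusted p = 2.7e-05, limma, Benjamini-Hochberg). The call was lost with an estimated correlation (p = 0.0452, adjusted p = 0.773 with an estimated correlation). In this list 10 genes rose and 52 did not pass, and 21 rose adjusted over the list alone. WRKY50 (Os11g0117600) rose by 1.98 ± 0.39, WRKY53 (Os05g0343400) by 1.36 ± 0.25 and WRKY24 (Os01g0826400) by 0.86 ± 0.26. Among 96 bHLH genes 3 rose, 1 fell and 92 did not pass (11 and 1 adjusted over the list alone), with a median of 0.08 and a camera adjusted p of 0.048 in limma with Benjamini-Hochberg adjustment, against an adjusted p = 0.773 with an estimated correlation and 0.0849 with the 4 local backgrounds replaced. The bHLH list passed in 10 of 20 settings. The bHLH gene Os01g0705700, described as similar to ICE1, rose by 1.81 ± 0.51. The member that fell, Os01g0928000 (-0.33 ± 0.06), has the same description. Os01g0108600 rose by 0.64 ± 0.06, and its 2 probes gave 0.20 and 0.64.

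NAC, MYB and ethylene-related genes were not called by camera (adjusted p = 0.342, 0.419 and 0.725, Benjamini-Hochberg, limma), although single members changed. The directional test of fry, which does not compare a list with the other genes, called the NAC list higher (adjusted p = 0.0192, limma with Benjamini-Hochberg adjustment). Of 60 genes in the NAC list 4 rose, 1 fell and 55 did not pass (7 and 1 adjusted over the list alone). The NAC domain genes Os11g0126900 (2.43 ± 0.49) and Os01g0816100 (2.41 ± 0.57) rose, and the member that fell, Os03g0121700 (-0.34, and 0.19 with median centring in place of loess), encodes an alpha-NAC protein, a ribosome-associated factor and no NAC transcription factor. Of 127 MYB genes 6 rose and 3 fell (19 and 8 adjusted over the list alone), with Os04g0517100 at 0.88 ± 0.10 and Os07g0634900 at -0.57 ± 0.03 (-0.14 with median centring). Of 81 ethylene-related genes 7 rose and 2 fell (14 and 6 adjusted over the list alone), among them the EIN3 family gene Os07g0685700, of transcription factors in ethylene signalling, at 0.81 ± 0.16.

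Phenylpropanoid and lignin genes included 6 of 57 that rose and 51 that did not pass (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0799, limma, Benjamini-Hochberg). Phenylalanine ammonia-lyase, the entry enzyme of the pathway, rose for Os05g0427400 (1.95 ± 0.67) and Os02g0627100 (1.86 ± 0.38, with its probes between 0.47 and 1.86), and cinnamoyl-CoA reductase Os09g0262000 rose by 1.14 ± 0.33. With the 4 local backgrounds replaced, Os09g0262000 rose by 1.35 ± 0.70, with line 2 at 2.16. Flavonoid genes went both ways, with 2 of 37 higher and 3 lower (7 and 6 adjusted over the list alone). Chalcone synthase Os07g0526400, named above, rose, whereas flavonoid 3'-monooxygenase Os10g0320100 fell by 0.62 (SD 0.11, and by 0.25 with median centring). Of 63 genes in the class III peroxidase list, 8 rose and 3 fell (19 and 8 adjusted over the list alone), led by the anionic peroxidase gene Os04g0688100 (1.68 ± 0.34). Those that rose included Os12g0448900 (0.77 ± 0.21), described as an animal haem peroxidase family protein, which is no class III peroxidase. Of 178 cytochrome P450 genes 5 rose and 4 fell (9 and 7 adjusted over the list alone). Glutathione transferases and redox enzymes had 3 of 160 higher and 10 lower (12 and 17 adjusted over the list alone), for example glutathione S-transferase Os07g0468100 at -0.55 ± 0.05 (-0.13 with median centring) and the glutaredoxin gene Os01g0667900 at 0.84 ± 0.28.

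Single genes of the lists of other hormones, transport and cell wall changed. Of 102 auxin genes 6 rose (10 adjusted over the list alone), including auxin response factor 3 (Os06g0677800, 0.59 ± 0.06) and the SAUR gene Os04g0662400 (2.10 ± 0.92, and 2.87 ± 0.41 with the 4 local backgrounds replaced). Of 56 genes of abscisic acid and dehydration 7 rose and 1 fell (12 and 1 adjusted over the list alone), with the LEA protein gene Os05g0542500 at 1.42 ± 0.41. With the 4 local backgrounds replaced, that gene had 1.87 ± 1.03, with line 2 at 2.98. Of 26 gibberellin genes 3 rose (5 higher and 2 lower adjusted over the list alone). Among 55 genes for phosphate, potassium, sodium and sulfate transport 3 rose (9 adjusted over the list alone), namely the potassium transporter genes Os09g0448200 (1.52 ± 0.62) and Os04g0401700 (1.19 ± 0.40) and the phosphate transporter gene Os03g0150600 (0.64 ± 0.25). Of 46 nitrogen genes 3 rose (6 adjusted over the list alone), among them asparagine synthetase Os03g0291500 (0.51 ± 0.03) and NADH-dependent glutamate synthase Os01g0681900 (0.40 ± 0.07, with 1 of its probes at -0.04). The MtN3-like gene Os08g0535200, of a family of sugar transporters, rose by 1.12 ± 0.39 in a list of 73 sucrose and sugar genes with 3 higher and 1 lower (3 and 2 adjusted over the list alone). Of 15 aquaporin genes 3 rose (4 adjusted over the list alone), and of 83 cell wall loosening genes 3 rose (4 higher and 1 lower adjusted over the list alone), including the endoglucanase gene Os07g0440100 (0.75 ± 0.18). None of these lists was called by camera. Of the 42 lists tested, 12, none of them called, had a median or a mean of the other sign than the test's direction, with medians from -0.022 to 0.022, and those for flavonoids, class III peroxidases, cytochromes P450, heat shock proteins and redox enzymes are among them.

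Genes for ribosomal proteins and for chlorophyll synthesis moved down as groups relative to genes of the same brightness, while with median centring in place of the brightness-dependent correction their medians turned to 0.33 and 0.14, against 0.17 for all genes. The ribosomal list was then called higher (camera adjusted p = 0.00508, limma, Benjamini-Hochberg) and the chlorophyll list was not called (0.437). With median centring and the 4 local backgrounds replaced, neither was called and the medians were 0.05 and -0.05, against 0.08 for all genes. Of 300 ribosomal protein genes 25 fell and 275 did not pass, and 91 fell adjusted over the list alone (median -0.19; camera adjusted p = 2.35e-25, limma, Benjamini-Hochberg; p = 0.158, adjusted p = 0.773 with an estimated correlation). After replacement of the 4 local backgrounds 67 fell and 1 rose. Their median was -0.25 in line 2, -0.04 in line 3 and -0.29 in line 4. The 50S protein L6 gene Os03g0751400 fell by 0.67 (SD 0.09, and by 0.23 with median centring) and the chloroplast 30S protein S6 gene Os03g0843400 by 0.55 (SD 0.03, and by 0.03 with median centring). Of 13 genes for chlorophyll and tetrapyrrole synthesis 4 fell and 9 did not pass (1 higher and 7 lower adjusted over the list alone; median -0.24; camera adjusted p = 0.00187; p = 0.058, adjusted p = 0.773 with an estimated correlation). They included uroporphyrinogen decarboxylase Os01g0622300 (-0.47 ± 0.11, and -0.08 with median centring) and magnesium chelatase subunit chlI Os03g0563300, which inserts magnesium into the chlorophyll precursor (-0.45 ± 0.05, and 0.14 with median centring). Among 177 heat shock and chaperone genes 9 fell (2 higher and 12 lower adjusted over the list alone), led by the chaperonin genes Os12g0277500 (-0.71 ± 0.12), Os02g0781400 (-0.65 ± 0.16) and Os10g0566700 (-0.60 ± 0.03), of proteins that fold others. Median centring left -0.03, -0.14 and -0.08 for these, and none passed. The photosynthetic light reactions, with 1 of 45 genes lower and 44 not passing (2 lower adjusted over the list alone), were not called, and with the 4 local backgrounds replaced 4 fell and 1 rose.

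**Figure D3:**
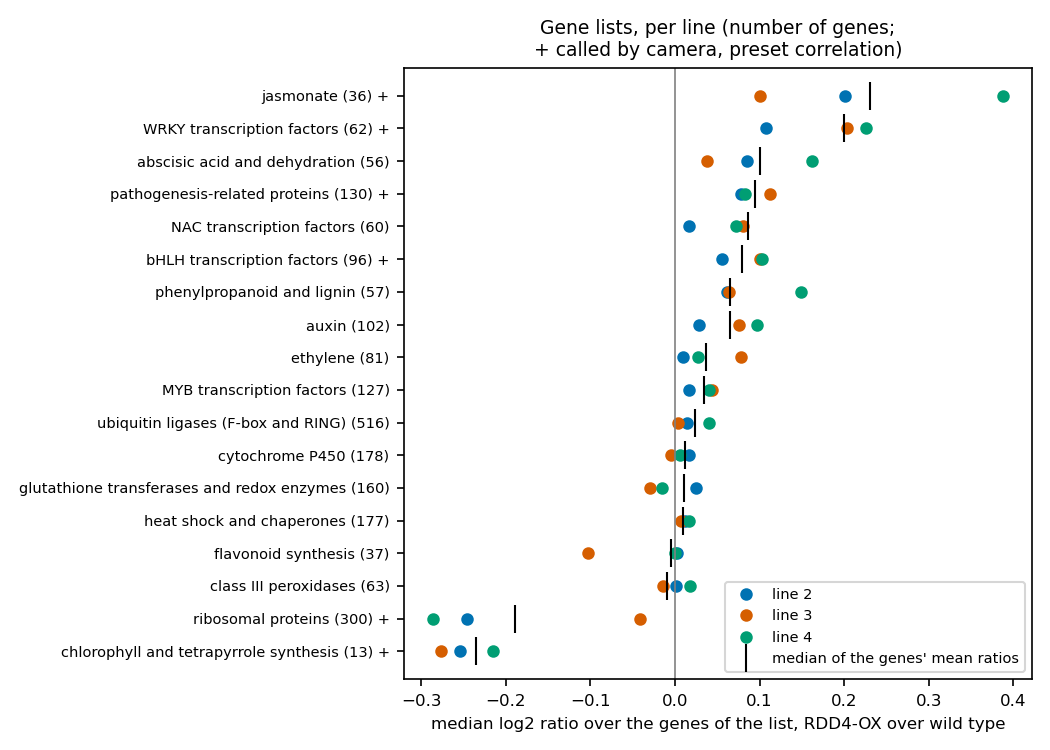
Median log2 ratio of RDD4-OX over wild type over the genes of each list (x axis), 1 point per line and a bar for the median of the genes' mean ratios, for the lists called by camera and those with at least 5 changed members (y axis). The ribosomal protein list lies at -0.25 and -0.29 in lines 2 and 4 and at -0.04 in line 3, and turns to 0.33 with median centring.

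The Dof family was set out gene by gene because RDD4 belongs to it. The files pair no gene of the array with the symbol RDD4, so the overexpressed gene was not identified and the labels were not checked by it. Of 18 Dof genes tested 4 changed, 2 in each direction, over all genes and adjusted over the list alone. Os10g0496000 rose by 0.44 ± 0.04 and Os04g0678400 by 0.39 ± 0.11, whereas Os08g0490100 fell by 0.51 (SD 0.10, and -0.00054 with median centring, not passing) and Os03g0169600 by 1.19 (SD 0.34). After replacement of the 4 local backgrounds 2 rose and 3 fell, and Os10g0496000 had 0.59 ± 0.25. The 4 probes of Os03g0169600 lay between -1.23 and -0.77. No Dof gene tested rose 2-fold, and the list was not called (camera adjusted p = 0.752, limma, Benjamini-Hochberg). Os02g0252400, singled out after its values were seen, was not well above background in Cy3 on any array and was well above it in Cy5 on 2 arrays, and its 2 probes had log2 ratios of 1.12 and 1.13 in line 3, 0.07 and 0.08 in line 2 and -0.13 and 0.003 in line 4. With the 4 local backgrounds replaced they had 1.27 and 1.32 in line 2. The sizes of these ratios rest on background, and no bound was given because the gene was not tested.

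Across the 23871 genes, the log2 ratios of the lines correlated with r = 0.587 between lines 2 and 3, 0.577 between lines 2 and 4 and 0.713 between lines 3 and 4. Genes are not independent replicates, and wild-type RNA shared by the arrays would raise these values. A dye effect of single probes would also raise them, since the dyes were the same way round on every array. With the 4 local backgrounds replaced, the correlations were 0.721, 0.705 and 0.713. Of the markers of other tissue that a leaf sheath sample could hold, 0 of 6 measured genes of floral organs, 0 of 4 of meristems and 0 of 3 of roots passed in limma with Benjamini-Hochberg adjustment (0, 0 and 1 at an unadjusted p under 0.05). The root gene RCc3 (Os02g0662000) lay at -0.56 ± 0.86. With the 4 local backgrounds replaced, the HKT-type sodium transporter gene Os06g0701700 of the root list rose by 1.05 (adjusted p = 0.0133, limma with Benjamini-Hochberg adjustment). In all, 36 of the 42 lists were not called, with adjusted p-values from 0.0646 to 0.952 in camera with Benjamini-Hochberg adjustment (limma).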

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

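The values in this part come from probes and spots that the comparison of genes does not use, and they were looked at after its results were seen. Of the 510 probes for microRNA loci, 108 (21.2%) were well above background on all 3 arrays in a channel, against 0 of 153 negative control spots. With the 4 local backgrounds replaced, the probe for the 3' stretch of the osa-miR419 locus had a log2 ratio of 1.46 ± 0.24 (SD, n = 3; limma over the 108 probes, Benjamini-Hochberg adjusted p = 4.2e-05). In the planned analysis it had 1.11 ± 0.81 and did not pass (adjusted p = 0.499, limma with Benjamini-Hochberg adjustment). With the same backgrounds replaced, the probe for the 5' stretch of that locus had 0.21 ± 0.30, with line 3 at -0.13, and did not pass (adjusted p = 0.259). The probe for the 3' stretch of the osa-miR414 locus had -0.29 ± 0.05 (adjusted p = 0.0401, limma with Benjamini-Hochberg adjustment), against 0.11 and 0.07 for its other probes, and in the planned analysis it had -0.18 ± 0.14 and did not pass (adjusted p = 0.499).

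The spike-in transcripts, added at known ratios, were read from the file headers' regression of observed on expected log ratios. Its slope was 0.862, 0.851 and 0.857 for lines 2, 3 and 4, and its intercept was -0.476, -0.701 and -0.677 on the log2 scale. These intercepts were singled out because they lay below 0 on all 3 arrays.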

How the results depend on the processing

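Analyses with the 4 local backgrounds replaced were chosen only after the results were seen. The planned analysis called 883 genes, 119 of them changed at least 2-fold, 4 Dof genes and 6 gene lists, with a mean correlation between lines of 0.626 and 23 genes named by size past the threshold. Array weights, the filters on dim probes, the mean of probes and trend with robust estimation kept each of these counts within 1.5 times. Aquantile normalisation gave the same counts, but it changes the average signal and leaves the log2 ratio of a spot as it was. It and the series matrix values, which repeat the LogRatio, count among the 20 settings without being separate checks. Without background correction 3835 genes were called (349 at least 2-fold, r = 0.715), with the scanner's processed signals 2711 (623, r = 0.742), and with its LogRatio, as with the series matrix values, 2949 (594, r = 0.736), of which 1460 were higher and 1489 lower. With normexp offset 0, 48 genes were called, 37 of them at least 2-fold, 11 of the 23 named genes, and 0 Dof genes in limma (7 at an unadjusted p under 0.05). Median centring in place of loess moved the median of all genes from 0.0203 to 0.167 and called 3499 genes, 1478 higher and 2021 lower (42.2% higher against 62.1%), 532 of them at least 2-fold, 2 Dof genes and 11 lists. Scaling between arrays left 0 genes, 0 at least 2-fold, 0 Dof genes and 0 of the named genes in limma (4008 genes and 7 Dof genes at an unadjusted p under 0.05), and 2 lists. With every probe on its own 1530 probes were called (187 at least 2-fold, 12 lists), and the separate-channel analysis called 2271 genes, with warnings that its variance estimate did not converge for some genes. Leaving out each line in turn gave 27 to 1095 genes, 27 to 292 at least 2-fold, 0 to 3 Dof genes, 5 to 10 lists, correlations of 0.573 to 0.713 and 9 to 22 of the named genes. Without replicate 2 (line 3) 27 genes were called, and without replicate 3 (line 4) 120, both pairs keeping the line 2 array. With fewer arrays, fewer degrees of freedom remain. Camera with an estimated correlation called 0 lists in limma (1 at an unadjusted p under 0.05). With 3 arrays it rests on 2 residual degrees of freedom, so a call among 42 lists was hardly within reach. Its lost calls therefore cannot tell whether a list moved. Fry called 36 lists for changes in either direction. For changes in 1 direction fry called 4 lists, namely NAC, bHLH and phenylpropanoid genes as higher and heat shock genes as lower. The 5 others called by camera had fry adjusted p-values of 0.0553 (chlorophyll), 0.0661 (WRKY), 0.0938 (jasmonate), 0.152 (ribosomal) and 0.164 (pathogenesis-related) in limma with Benjamini-Hochberg adjustment.

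With the 4 local backgrounds replaced 3771 genes were called, 339 of them at least 2-fold, with a mean correlation of 0.713. That count became 1095, 429 and 1107 without replicates 1, 2 and 3, and 10311 with median centring (6509 higher and 3802 lower), while stricter filtering, trend with robust estimation and a correction for probe GC content kept it within 1.5 times. Under median centring in the planned analysis the ribosomal protein list turned to a median of 0.328 and was called higher (camera adjusted p = 0.00508, limma, Benjamini-Hochberg), and the chlorophyll list turned to 0.135 and was not called (0.437). Genes that turned there were Os03g0337600 (0.00978), Os03g0563300 (0.135), Os05g0349700 (0.116), Os06g0196900 (0.249), Os12g0175500 (0.0956), Os02g0192700 (0.0978), Os05g0499400 (0.00742), Os03g0121700 (0.193), Os06g0683200 (0.0893) and Os04g0461100 (0.12), none of these genes past the threshold. With every probe on its own, the first listed probe of the sucrose transporter gene Os03g0170900 had -0.212, against 0.43 for its brightest. Over the single genes and lists compared, 118 in all for most settings, 96 lost their call without replicate 2. Without replicate 3 it was 74 and without replicate 1 it was 31, in no case with a change of direction. The single genes compared had the same sign in all 3 lines, so 2 lines could hardly give another direction. Where not stated, the cause of a change was not tested. The slide as a random block was not run because all 3 arrays lay on 1 slide, and no paired analysis was possible because there is only 1 group of ratios. Signal over background limits what can be said of the dimmest genes.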

Other observations

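Tests with the 4 local backgrounds replaced, and those of the dim genes by the scanner's LogRatio, of the Dof family, of the classes of ribosomal proteins and of neighbouring genes, were chosen only after the results were seen. In that added analysis the naming rule took further genes. PGPS/D12 (Os03g0830500) and an esterase/lipase domain gene (Os07g0526600) were not well above background in the wild type on any array. Their means were 13.8-fold and 9.23-fold higher in the overexpressing plants (limma, Benjamini-Hochberg adjusted p = 0.000462 and 0.0029). The bounds for these genes equalled the fitted means, so they are no lower limits for single lines. Their lowest log2 ratios were 3.63 in line 2 and 2.69 in line 3. The oleosin gene Os04g0546500, of proteins that coat lipid bodies, rose by 3.44 ± 0.69, and its 6 probes lay between 3.19 and 3.45. The carboxyl methyltransferase family gene Os06g0242000 rose by 3.21 with an SD of 1.7. It had 5.20 in line 2, against 2.23 and 2.19 in lines 3 and 4. WRKY28 (Os06g0649000), whose probe shares a stretch of 20 bases with a probe of 1 other locus, rose by 2.36 ± 0.19 and WRKY19 (Os05g0571200) by 2.03 ± 0.31, and 25 of 62 WRKY genes rose (30 higher and 1 lower adjusted over the list alone). Further genes fell, namely the FAD-dependent oxidoreductase gene Os08g0519100 by 3.05 (SD 0.43), the extensin-like gene Os05g0552600 by 2.99 (SD 0.06), and the agglutinin gene Os04g0173800 by 2.27 (SD 0.18). The ubiquitin domain gene Os09g0452700 also fell, and because it was well above background in Cy5 on only 1 array, the size of its change rests on background. Another ubiquitin domain gene, Os09g0483200, was not well above background in the overexpressing plants on any array and was at least 2.71-fold brighter in the wild type (adjusted p = 0.000464, limma with Benjamini-Hochberg adjustment).

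Ribosomal protein genes were split by their description. The 48 genes described as 30S, 50S, chloroplast or plastid had medians of -0.19, -0.30 and -0.25 in lines 2, 3 and 4, and 16 of them fell, whereas the 157 genes described as 40S or 60S had medians of -0.27, -0.03 and -0.31, and 4 fell. In the added analysis 21 and 25 fell, so the size of the contrast between 16 and 4 depended on the 4 local backgrounds. With median centring the medians of the mean ratios turned to 0.27 and 0.36. The difference between these classes was not tested. In the added analysis, genes that rose at least 2-fold lay next to each other in locus order in 29 pairs, against a mean of 3.55 and at most 11 in 10000 permutations of the genes (one-sided permutation p = 1e-04, the smallest they can give). Without genes whose probe shares a stretch of 20 bases with a probe of another locus, which took out every pair of a run from Os02g0559800 to Os02g0561900, there were 22 pairs against a mean of 3.06 (permutation p = 1e-04). In the planned analysis there were 2 such pairs (permutation p = 0.08), and without those genes, which makes new neighbours, 3 (p = 0.01). Binding of related transcripts to shorter stretches was not tested.

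On the line 2 array alone, the ratios of dim genes lay close to 0 in the planned analysis. Over the 7957 dimmest genes their SD was 0.0939, against 0.303 and 0.374 for lines 3 and 4. By the scanner's LogRatio line 2's SD was not smaller, at 1.16 times the mean of the other lines'. Such an SD holds noise as well as response, so it cannot decide whether dim genes responded less in line 2. With the 4 local backgrounds replaced, line 2's SD was 1.26 times that mean, and with the same 4 backgrounds copied onto the line 3 array its SD dropped to 0.146 times its own value, in line with a noise estimate spoiled by 4 spots. A response of line 2 above or below that of the other lines stays open as a biological difference between lines and was not tested.

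The ribosomal protein list lay lower in the overexpressing plants by its median of -0.19. A trend of the ratio with brightness and the GC content of the probes are argued against as the whole cause, since the median lay at percentile 0 of 10000 random lists matched on brightness (lowest -0.0211) and at percentile 0 of those matched on brightness and probe GC content (lowest -0.029). With median centring, the list's 0.33 lay below the 0.53 of brightness-matched genes by about the same distance (difference -0.206, and -0.213 in the planned analysis). A dye effect of single probes cannot be told apart from the genotype, because 0 arrays had the dyes exchanged. An effect of RDD4 overexpression stays open, untested, and may not be shared by line 3, where the median was -0.04. That doubt does not cover the genes described as 30S, 50S, chloroplast or plastid, whose median in line 3 was -0.30. Those described as 40S or 60S had -0.03 there.

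None of the 18 Dof genes tested rose 2-fold, although RDD4, a Dof gene, was overexpressed per the labels. Dyes reversed against the labels would need a strongly lower Dof gene, and the lowest lay at -1.19 (Os03g0169600). That value does not settle it, because the probe of RDD4 is not identified and could lie outside the overexpressed stretch. Of 31 Dof probes, 23 have a name that gives coding sequence and 3' untranslated region, and only 2 one that gives coding sequence alone. A construct of coding sequence alone may lack the 3' untranslated region. Whether these names describe the probe or the whole transcript is not given, so they do not show where the probes lie. The gene Os02g0252400 was too dim to be tested. With the 4 local backgrounds replaced, its probes lay at 1.27 and 1.32 in line 2 and 1.12 and 1.13 in line 3. In line 4 they lay at -0.13 and 0.003. Its Cy3 signal was not well above background on any array. The sizes of these ratios therefore rest on background and cannot settle whether it is RDD4. These explanations stay open and cannot be told apart with these arrays, as does a weak overexpression, which was not tested.

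Turning the sign of single arrays gives 4 sign patterns of the 3 arrays, the real one included, too few for a share under 0.05. In the planned analysis the real pattern gave 883 genes and 119 at least 2-fold, and the highest other pattern 0 and 0 in limma (at most 149 genes at an unadjusted p under 0.05). These were 3771 and 339 against 0 and 0 with the 4 local backgrounds replaced (at most 218 at an unadjusted p under 0.05). In each case 1 of the 4 patterns, the real one, gave as many genes.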
